A study of Fundulus heteroclitus with 15 samples.

How the data were processed

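Liver RNA of adult female mummichog from a 14-day waterborne exposure to EE2 (0, 50 or 250 ng/L) was measured on 15 Agilent 1-colour arrays, 5 per group. Per the labels, RNA was labelled with Cy3 and the arrays of a group were biological replicates; the labels give no replicate numbers, so arrays are numbered within a group and no array is paired with another. Per the file headers, the deposited intensity values were extracted from the scans with Agilent Feature Extraction 10.7.1.1 (protocol GE1_107_Sep09), which subtracts background and detrends each spot without normalizing between arrays. The processed signal, the median spot signal, the local background median and the flags for saturation, outliers and signal well above background were used. A table of values deposited by the authors holds log2 values whose columns have nearly equal distributions (column medians of 7.66 to 7.7) and correlate at 0.998 to 1 with the log2 processed signal of the same array. It resembles quantile normalization between arrays, but the steps that made it are not given in the sources used here, and it served as an alternative only. All its columns matched a labelled array, leaving 0 unused.

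Each probe has 2 spots, whose values correlated at 0.989 to 0.999 within arrays. Control spots and spots with an outlier flag (0 to 29 per array) were left out, and the other spots of a probe were averaged. No spot was saturated: the flag was set on 0 spots, and the highest processed signal was 749634 against a scanner limit of 777980. The log2 processed signal minus the array's own 75th percentile was the level used, without a pseudocount. Of 7152 probes, 6145 were well above background on at least 5 of the 15 arrays and were tested; 5133 were so on all 15. The array also holds 5 custom control probes, which were kept out of the comparisons. Dim probes have signals near background, so their fold changes are the least certain. Where no array of a group was well above background for a probe, the fold is a bound: the bright group's mean level against the dim group's mean of, per array, the higher of the probe's own level and the lowest level among probes well above background.

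Gene names are those in the array's design and can be old. Of 7157 probes including the custom controls, 4413 carry a gene name, 168 the name of a hypothetical protein and 2571 none; the names come to 3248 distinct genes. None of the 86 GenBank identifiers on the array matched the RefSeq gene table (0 matches), so names were kept as given. No genome was used here, so no positions are stated. Different probes of a gene were fitted separately, and where they differ in call this is stated.

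Groups were compared with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table). A mean per group was fitted to all 15 arrays with lmFit, giving 12 residual degrees of freedom, and eBayes moderated the variances. The contrasts were 50 ng/L against control, 250 ng/L against control, 250 against 50 ng/L, and the mean of both doses against control. Benjamini-Hochberg adjustment ran over all probes tested within a contrast, with a threshold of 0.05. Errors of shifts are standard errors from that fit (median 0.294) and errors of levels are SDs of 5 arrays. Apart from the tests and alternatives said below to have been chosen later, the comparisons, tests, gene lists, alternatives and naming rule were fixed before the data were examined. Under that rule, each comparison names up to 10 genes that rose most and 10 that fell most among called probes with a gene name. All arrays of each group had to lie beyond the other group's mean. The brightest probe meeting these conditions stood for its gene, so a brighter probe that was not called was passed over. Vitellogenins, zona pellucida proteins and estrogen receptors are always named, and for gene lists up to 4 members with the smallest p.

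The 24 gene lists covered pathways of liver and markers of other cell types, matched by name patterns to 557 gene names. Before any signals were compared, the matches were read and corrected by name: 34 names that had matched by accident were left out and 84 older names were added. Lists with 3 or more genes were tested with camera, 1 probe per gene (the brightest), with a preset correlation of 0.01 between genes. The p-values were adjusted over the 72 tests of 24 lists in 3 comparisons. Camera with an estimated correlation was run beside it: the vitellogenin and egg envelope list was the 1 list called with it in each comparison. Fry, which asks whether a list's genes move on balance 1 way, gave adjusted p = 4.75e-06 at 50 ng/L, 5.29e-08 at 250 ng/L and 0.000844 between the doses for that list. It gave 0.393, 0.0171 and 0.247 for cholesterol synthesis and 0.713, 0.0231 and 0.168 for endoplasmic reticulum folding and secretion. For the other lists that camera called at 250 ng/L, fry did not pass. Its adjusted p there was 0.168 for fatty acid synthesis, 0.272 for muscle, 0.334 for oxidative phosphorylation and 0.713 for exocrine pancreas.

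The scripts were tested on simulated data with the arrays' own spread, 50 probes of 6139 being changed per size. At 250 ng/L against control, log2 changes of 1, 2, 4 and 8 were called for 48%, 90%, 96% and 100% of them, with 7 false among 174 calls. At 50 ng/L, changes of 0.5, 1, 2 and 4 were called for 2%, 24%, 86% and 98%, with 1 false among 106. Between the doses, changes of 0.5, 1, 2 and 4 were called for 0%, 38%, 88% and 98%, with 6 false among 118. For the mean of both doses, changes of 0.75, 1.5, 3 and 6 were called for 22%, 84%, 94% and 100%, with 5 false among 155. A simulated list shifted by 0.5 was the 1 list called at 250 ng/L and between the doses (camera adjusted p = 2.66e-08 and 2.75e-08). At 50 ng/L, where no shift was put in, 0 were called. The simulated probes varied independently of each other. The simulation therefore cannot show how often camera calls lists by mistake when their genes vary together.

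Alternatives were normexp background correction (offset 50), quantile normalization, cyclic loess, scaling to the array median, the authors' values, no filter on dim probes, a filter requiring all 15 arrays, slide as a block, each slide alone (7 and 8 arrays), only the groups compared, eBayes with a trend and robust variances, array weights, and each array left out in turn. Normexp was planned on mean spot signals; the columns used here hold medians, so it ran on the median spot and background signals. For gene lists, the mean over all probes of a gene and an estimated correlation were also tried. The similarity of the effects at both doses was set beside 100 simulations without effect that shared the controls, and beside 20 splits of the controls.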

Results

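Gene expression was measured in livers of adult female mummichog (Fundulus heteroclitus), an estuarine killifish, after 14 days in water holding 17α-ethinylestradiol (EE2), the synthetic estrogen of contraceptive pills. There were 3 groups of 5 arrays: no EE2 (control), 50 ng/L and 250 ng/L. Per the labels, the arrays of a group were biological replicates, and each carried Cy3-labelled liver RNA on 7152 probes spotted 2 times each. Whether an array holds RNA of a single fish or of a pool is not given in the sources used here, so SDs are spreads among arrays. The arrays came on 2 slides, with 2 control, 2 low-dose and 3 high-dose arrays on slide 1 and 3, 3 and 2 on slide 2. Brightness differed between arrays: the 75th percentile of the processed signal ran from 545 (50 ng/L replicate 3) to 3576 (50 ng/L replicate 1), with geometric means of 1848 in controls, 1047 at 50 ng/L and 1365 at 250 ng/L. Between 75.6% (250 ng/L replicate 2) and 91.7% (250 ng/L replicate 4) of probes were well above background. Log2 levels correlated across probes at 0.934 to 0.979 between arrays of 1 group and at 0.926 to 0.972 between arrays of different groups. The smallest SD of log2 differences between 2 arrays was 0.721, so no 2 arrays held the same values. Levels are log2 signals relative to the array's own 75th percentile, and 5 arrays per group limit their precision. Every probe said to have risen or fallen at 50 or 250 ng/L had all 5 arrays of each group beyond the mean of the other group.

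The comparison of 50 ng/L with control asked which liver transcripts the lower concentration altered. Vitellogenins, the egg yolk precursors that fish liver makes under estrogen, rose most. Vitellogenin A2 rose by 6.33 ± 0.561 on the log2 scale (SE, n = 5 per group; 80.2-fold; limma adjusted p = 2.05e-05). Its level went from -6.28 ± 1.03 (SD) in controls, where 3 of 5 arrays were well above background, to 0.05 ± 1.22. A probe named only Vitellogenin rose by 6.27 ± 0.527 (77.3-fold), and 4 Vitellogenin I probes rose by 3.08 to 5.96 (8.46-fold to 62.2-fold). Of 3 Vitellogenin II probes 1 rose, by 2.90 ± 0.549 (limma adjusted p = 0.0203), while the others had shifts of 2.77 ± 0.651 (adjusted p = 0.0991) and -0.07 (adjusted p = 0.999). Transcripts for glycoproteins of the egg envelope rose too. The 4 probes for zona pellucida sperm-binding protein 4 (ZP4) rose by 2.32 to 2.88, and 2 of 3 probes for zona pellucida sperm-binding protein 3 (ZP3) by 1.57 and 1.65, with the third at -0.18. Serotransferrin I, an iron carrier of plasma, rose by 2.93 ± 0.411 (7.62-fold; limma adjusted p = 0.00182). WAP four-disulfide core domain protein 2 (WAP2), of a family of small secreted proteins that includes protease inhibitors, rose by 3.67 ± 0.515 (12.7-fold) on 1 of its 3 probes. Probes that the array's design names for gamma-gliadin (a wheat storage protein), App1 protein and TraD protein (of bacterial conjugation) rose by 2.84, 2.84 and 2.72. Within groups, 9 probes with such names correlated with the ZP4 probes at a median r of 0.852. The 2 probes for estrogen receptor alpha, a nuclear receptor that EE2 binds, had shifts of 0.69 ± 0.505 and 0.63 ± 0.464 (limma adjusted p = 0.999 for both). On slide 1 their shifts were -0.71 and -0.55, and on slide 2 they were 1.63 and 1.42. The 2 probes for estrogen receptor beta A had shifts of -0.03 and -0.10 (adjusted p = 0.999 for both).

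In all, limma called 34 of 6145 probes at 50 ng/L, 34 higher and 0 lower, each changed 2-fold or more; 30 of them carry the names of 20 genes. At an unadjusted p under 0.05 there were 252 probes, against 307 expected by chance. Quantile normalization, the authors' values and the fits without control replicate 2, control replicate 5 or 50 ng/L replicate 1 each called 1 probe lower. So did leaving out control replicate 2 and 250 ng/L replicate 3, which lie farthest apart in exocrine pancreas markers. With slide as a block 34 probes were called and the shifts were the same. Within slide 1, where both of these groups have 2 arrays, 3 were called, and within slide 2, 25. On slides 1 and 2, Vitellogenin A2 was shifted by 7.13 and 5.79, Vitellogenin by 7.16 and 5.68, and the Vitellogenin I probe with the largest rise by 6.75 and 5.43. Serotransferrin I was shifted by 2.20 and 3.42, WAP2 by 2.97 and 4.14, and the brightest ZP3 probe by 1.61 and 1.67. Without control replicate 3, 22 probes were called. The Vitellogenin II call ended without control replicate 1, 3 or 4 or 50 ng/L replicate 3 or 4 (shifts of 2.49 to 3.31). The call of 1 ZP4 probe (2.32; adjusted p = 0.0293) ended without control replicate 1, 2, 3 or 4 or 50 ng/L replicate 1, 3, 4 or 5 (2.07 to 2.62).

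Among gene lists fixed beforehand, the vitellogenin and egg envelope list shifted most at 50 ng/L, with 5 of its 6 genes higher past the test over all probes and 6 when adjusted over the list alone. Its mean shift was 3.83 (camera adjusted p = 1.35e-29; adjusted p = 0.000815 with an estimated correlation), with 3.72 on slide 1 and 3.90 on slide 2. The 8 genes of cholesterol synthesis had a mean shift of 0.516 (7 higher; camera adjusted p = 0.00322; adjusted p = 0.516 with an estimated correlation). None of them passed the limma test alone (0 genes), and HMG-CoA reductase and lanosterol demethylase (CYP51) had shifts of 0.86 and 0.87. Their list shifted by 0.124 on slide 1 and 0.777 on slide 2, and the call ended within slide 1 (adjusted p = 0.697) and with normexp (adjusted p = 0.0582). The 29 genes of endoplasmic reticulum folding and secretion, which take secreted proteins through folding and export, had a mean shift of 0.282 (21 higher, 0 past the limma test; camera adjusted p = 0.0141; adjusted p = 0.787 with an estimated correlation). It was 0.23 on slide 1 and 0.316 on slide 2. That call ended without control replicate 1 (0.243), 3 (0.223) or 5 (0.192) or 50 ng/L replicate 1 (0.265), with normexp (adjusted p = 0.571) and on either slide. The 7 genes of steroid and bile acid metabolism had a mean shift of 0.473 (camera adjusted p = 0.0201; adjusted p = 0.188 with an estimated correlation), 0.468 and 0.476 within slides. StAR, which carries cholesterol into mitochondria, was the 1 member past the test when adjusted over the list alone, with 0 over all probes. The call ended on either slide, with normexp (adjusted p = 0.524) and without control replicate 1 (0.395) or 50 ng/L replicate 4 (0.421). Markers of exocrine pancreas, tissue that in many fishes lies within or beside the liver, also shifted. In this list 19 of 20 genes were higher, by 0.989 on average (camera adjusted p = 0.000117; adjusted p = 0.787 with an estimated correlation). The shift was 1.81 on slide 1 and 0.445 on slide 2. Elastase 2A and amylase, digestive enzymes of that tissue, had shifts of 1.43 and 1.36, and 0 passed the limma test. Without control replicate 2, where these markers were lowest, the mean shift was 0.317 (adjusted p = 0.343). The 20 muscle markers shifted by 0.246 (0 past the limma test; camera adjusted p = 0.0459; adjusted p = 0.787 with an estimated correlation), with -0.134 on slide 1 and 0.499 on slide 2. Quantile, cyclic loess and median scaling each ended that call (adjusted p = 0.0647, 0.125 and 0.0502). It also ended without control replicate 3, 4 or 5, 50 ng/L replicate 1, 3 or 5 or 250 ng/L replicate 1 or 2 (shifts of 0.162 to 0.255).

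**Figure D1:**
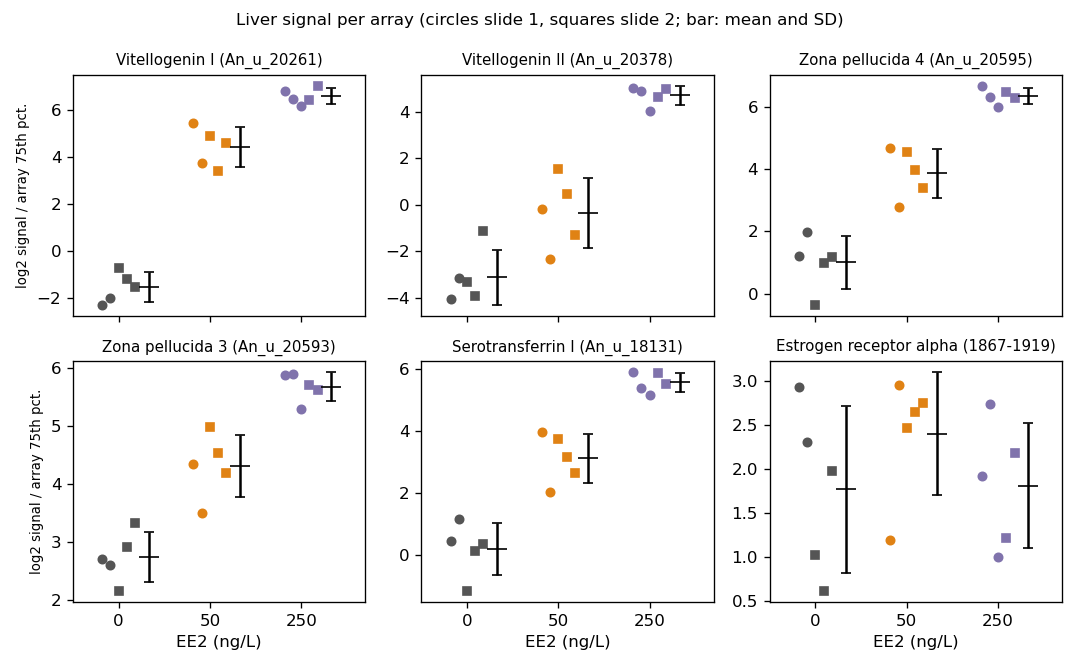
Log2 level relative to the array's 75th percentile (vertical axis) by EE2 group (horizontal axis) for 6 probes: 1 for Vitellogenin I, Vitellogenin II, ZP4, ZP3, Serotransferrin I and estrogen receptor alpha each. Points are single arrays (circles slide 1, squares slide 2), with the mean and SD of 5 arrays. Mean Vitellogenin II levels are -3.13, -0.36 and 4.73, and those of the estrogen receptor alpha probe shown are 1.77, 2.40 and 1.81.

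At 250 ng/L the same question was asked of the higher concentration. The probe named Vitellogenin rose by 8.92 ± 0.527 (SE, n = 5 per group; 484-fold; limma adjusted p = 1.05e-07), from -4.44 ± 0.878 (SD) to 4.48 ± 0.376. Vitellogenin A2 rose by 8.82 ± 0.561 (452-fold), 2 Vitellogenin II probes by 7.85 ± 0.651 (231-fold) and 7.48 ± 0.549 (178-fold), and the 4 Vitellogenin I probes by 4.01 to 8.11 (16.1-fold to 276-fold). The smallest of these Vitellogenin I rises, 4.01 and 4.24, were on the 2 brightest probes, whose levels within exposed groups fell with array brightness (median slope -0.487 per log2 unit). The median slope was -0.383 for 68 other probes that bright and 0.00892 for 1256 probes at levels of 0 to 4. The third Vitellogenin II probe had a shift of -0.25 (limma adjusted p = 0.633). ZP4 rose by 4.18 to 5.35 on 4 probes (largest 40.9-fold; adjusted p = 9.77e-07), and ZP3 by 2.94 ± 0.268 (7.67-fold) and 2.87 ± 0.272 on 2 of 3 probes, with the third at -0.30 (adjusted p = 0.58). WAP2 rose 63.9-fold, whey acidic protein, named for a milk protein, by 5.39 ± 0.716 on the log2 scale and WAP four-disulfide core domain protein 3 (WAP3) by 5.35 ± 0.791. Serotransferrin I rose by 5.39 ± 0.411 (41.9-fold), and the probes named for TraD, gamma-gliadin and App1 by 5.19, 5.18 and 5.12. Estrogen receptor alpha had shifts of 0.52 and 0.04 (adjusted p = 0.722 and 0.977) and estrogen receptor beta A of -0.15 and -0.29 (adjusted p = 0.81 and 0.581).

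Fewer named genes fell at 250 ng/L. Small inducible cytokine A4 homolog, a chemokine, fell by 3.09 ± 0.58 on 1 of 2 probes (n = 5 per group; limma adjusted p = 0.00549), from 5.01 ± 0.688 to 1.93 ± 0.827. Beta-galactosidase, a lysosomal enzyme, fell by 3.03 ± 0.509 (adjusted p = 0.00201), and dynactin subunit 2, of the complex that links dynein to its cargo, fell by 1.81 ± 0.252 on 1 of 3 probes (adjusted p = 0.000309). Mitochondrial ribosomal protein L11 fell by 1.60 ± 0.245 (adjusted p = 0.000849), a call that ended with normexp (-0.92; adjusted p = 0.0608). Formimidoyltransferase-cyclodeaminase, a histidine-degrading enzyme of liver, fell by 1.09 ± 0.261 (adjusted p = 0.0344), and KIAA0853 by 1.03 ± 0.22 on 1 of 2 probes (adjusted p = 0.0167), the other being at 0.68 (adjusted p = 0.634). Cytokine receptor common gamma chain, a subunit shared by several interleukin receptors, fell by 1.02 ± 0.184 (adjusted p = 0.00365), G patch domain containing 1 by 0.96 ± 0.184 (adjusted p = 0.00702) and retinol dehydrogenase 13 by 0.90 ± 0.2 (adjusted p = 0.0204). Hemoglobin alpha-D chain, a globin of red blood cells, was not well above background on any array at 250 ng/L and was at least 1.69-fold lower there (fitted shift -1.45; adjusted p = 0.0373). Normexp gave 0.078 for it and the slide block an adjusted p of 0.0547. Leaving out 1 array ended the calls of hemoglobin alpha-D (control replicate 1, 2, 3 or 5, 50 ng/L replicate 3 or any 250 ng/L array; -1.68 to -1.22) and formimidoyltransferase-cyclodeaminase (control replicate 1, 3 or 5 or 250 ng/L replicate 2, 3 or 4; -1.20 to -0.95). It also ended those of KIAA0853 (control replicate 1 or 3 or 250 ng/L replicate 5; -1.19 to -0.94) and retinol dehydrogenase 13 (control replicate 1 or 3 or 250 ng/L replicate 1 or 5; -0.97 to -0.82). The call of formimidoyltransferase-cyclodeaminase also ended with cyclic loess, without the 2 arrays farthest apart in pancreas markers and with the mean pancreas marker level as a covariate.

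Limma called 166 of 6145 probes at 250 ng/L, 126 higher and 40 lower (75.9% higher), of which 140 changed 2-fold or more; 94 named genes were among them, 78 higher and 16 lower. The higher share was 67.4% with quantile normalization (130 higher, 63 lower) and 65.8% with the authors' values (127 and 66). With array weights 317 probes were called, of which 62.1% were higher (197 higher, 120 lower). Those weights depend on the order of the probes, and over 20 other orders the count was 292 to 339, with 60.2% to 64.7% higher. With slide as a block 159 probes were called, with 42 within slide 1 (41 higher) and 109 within slide 2 (94 higher). The block, slide 1 and slide 2 shifts were 9.05, 9.71 and 8.50 for Vitellogenin, 8.01, 8.28 and 7.62 for Vitellogenin II and 5.31, 4.74 and 5.79 for ZP4. They were 5.35, 4.69 and 5.93 for Serotransferrin I and 5.18, 3.96 and 6.37 for whey acidic protein. Among fallers they were -3.01, -2.48 and -3.57 for the cytokine A4 homolog, -3.16, -2.71 and -3.65 for beta-galactosidase, and -1.88, -1.59 and -2.19 for dynactin subunit 2. Within slide 1 the calls of whey acidic protein, WAP3, gamma-gliadin, App1 and the fallers other than beta-galactosidase ended. Within slide 2 those of beta-galactosidase, hemoglobin alpha-D, formimidoyltransferase-cyclodeaminase, the cytokine receptor, G patch domain containing 1 and retinol dehydrogenase 13 ended.

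All 6 vitellogenin and egg envelope genes rose at 250 ng/L, also when adjusted over the list alone. Their mean shift was 6.15 (camera adjusted p = 5.11e-24; adjusted p = 0.0012 with an estimated correlation), 6.21 with slide as a block and 6.41 and 5.95 within slides. In cholesterol synthesis 4 of 8 genes rose, and 4 when adjusted over the list alone. Among them were lanosterol demethylase (CYP51) by 2.59 ± 0.447 (6.02-fold; limma adjusted p = 0.00266), isopentenyl-diphosphate isomerase by 1.93 ± 0.427 and C-4 methylsterol oxidase by 1.54 ± 0.328. All 8 were higher, by 1.26 on average (camera adjusted p = 2.54e-06; adjusted p = 0.188 with an estimated correlation), 1.28 with slide as a block and 1.22 and 1.25 within slides. The isomerase call ended without control replicate 1, 3 or 5 or 250 ng/L replicate 1, 2 or 5 (1.78 to 2.30). The oxidase call ended without control replicate 3 or 250 ng/L replicate 5 (1.34 to 1.73), and the calls of these 3 genes ended within either slide. In endoplasmic reticulum folding and secretion 2 of 29 genes rose, and 8 when adjusted over the list alone. Protein disulfide-isomerase A4, a folding enzyme, rose by 2.01 ± 0.503 on 1 of 3 probes (adjusted p = 0.0454) and Sec61 beta, of the translocation channel, by 0.89 ± 0.209 (adjusted p = 0.03). In this list 27 genes were higher, by 0.752 on average (camera adjusted p = 4.86e-10; adjusted p = 0.188 with an estimated correlation), 0.773 with slide as a block and 0.731 and 0.808 within slides. The Sec61 beta call ended without control replicate 1, 2, 3 or 5 or 250 ng/L replicate 1, 3, 4 or 5 (0.77 to 0.99). That of the disulfide-isomerase ended without any of the arrays but control replicate 4 and 50 ng/L replicate 2 (1.70 to 2.50) and with slide as a block (adjusted p = 0.0526). Fatty acid synthesis had 6 of 7 genes higher, by 0.736 on average (0 past the limma test; camera adjusted p = 0.0306; adjusted p = 0.428 with an estimated correlation), 0.717 with the block and 0.625 and 0.851 within slides. A delta-5/delta-6 desaturase and fatty acid synthase had shifts of 1.20 (adjusted p = 0.192) and 1.02 (adjusted p = 0.433). That list call ended within slide 1 (adjusted p = 0.163) and without control replicate 1 (0.574) or 5 (0.691) or 250 ng/L replicate 1 (0.516) or 5 (0.689).

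Muscle markers shifted by 0.474 at 250 ng/L (camera adjusted p = 0.00318; adjusted p = 0.616 with an estimated correlation), 0.466 with slide as a block and 0.179 and 0.705 within slides. In that list 1 of 20 genes rose, a smooth muscle myosin heavy chain, by 1.43 ± 0.254 (limma adjusted p = 0.00354), which ended with normexp and with the authors' values. Oxidative phosphorylation had 64 of 83 genes lower, by a mean of -0.183 (0 past the limma test; camera adjusted p = 0.00425; adjusted p = 0.88 with an estimated correlation). With slide as a block it was -0.21, and within slides -0.447 and -0.017. The call ended without control replicate 1 (-0.131) or 2 (-0.099) or 250 ng/L replicate 2 (-0.159) and with cyclic loess (-0.082). Exocrine pancreas markers again had 19 of 20 genes higher, by 1.08 on average (0 past the limma test; camera adjusted p = 0.0012; adjusted p = 0.88 with an estimated correlation). Their shift was 1.2 with slide as a block, 2.34 on slide 1 and 0.09 on slide 2. Without control replicate 2 the shift was 0.408 and without 250 ng/L replicate 3 it was 0.645, and each ended the call. With both left out it was -0.027, and oxidative phosphorylation was at -0.098 (adjusted p = 0.233). Then 181 probes were called at 250 ng/L and 39 at 50 ng/L; with the mean pancreas marker level as a covariate 172 and 43 were called.

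**Figure D2:**
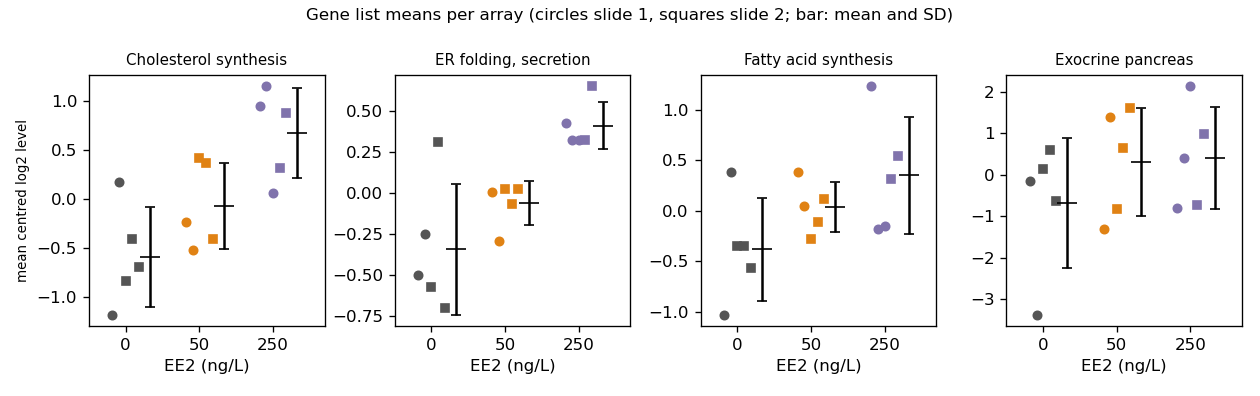
Mean log2 level of the genes of 4 lists on each array (vertical axis, relative to each gene's mean over the 15 arrays) by EE2 group (horizontal axis): cholesterol synthesis, endoplasmic reticulum folding and secretion, fatty acid synthesis and exocrine pancreas. Points are single arrays with the mean and SD of 5; in the pancreas panel control replicate 2 lies at -3.38 and 250 ng/L replicate 3 at 2.13.

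Between the exposed groups, the comparison asked what differed at 250 ng/L from 50 ng/L. Vitellogenin II rose further on 2 of 3 probes, by 5.08 ± 0.651 (SE, n = 5 per group; 33.9-fold; limma adjusted p = 0.00236) and 4.58 ± 0.549 (23.9-fold). The probe named Vitellogenin rose by 2.65 ± 0.527 (adjusted p = 0.0217), and Vitellogenin A2 by 2.49 ± 0.561 (adjusted p = 0.0455). A single Vitellogenin I probe rose by 2.15 ± 0.378 (4.45-fold; adjusted p = 0.00921), while the other 3 had shifts of 1.69, 0.99 and 0.93 (adjusted p = 0.272, 0.577 and 0.686). ZP4 rose on 3 of 4 probes by 1.74 to 2.48 and ZP3 on 2 by 1.37 and 1.23; Serotransferrin I rose by 2.46 ± 0.411. WDNM1, a small secreted relative of whey acidic protein, rose by 4.19 ± 0.608 (18.2-fold; adjusted p = 0.00314) and WAP3 by 3.91 ± 0.567 on 1 of 2 probes, with the other at 2.63 (adjusted p = 0.215). A probe named for an alpha-mannosidase rose by 3.72 ± 0.645, dihydropyrimidinase related protein 5 by 2.74, nucleolin, an abundant protein of the nucleolus, by 2.67 on 1 of 3 probes, atrophin-1 by 2.59 and phosphatidylinositol transfer protein beta by 2.50. Dynactin subunit 2 fell by 1.51 ± 0.252 on 1 of 3 probes (adjusted p = 0.00646) and disheveled associated activator of morphogenesis 1 (DAAM1), which links Wnt signalling to actin, by 0.88 ± 0.2 (adjusted p = 0.0471).

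Limma called 67 of 6145 probes between the doses, 65 higher and 2 lower at 250 ng/L, with 500 at an unadjusted p under 0.05, and 53 with slide as a block. Within slides, limma called 0 and 0, with 476 and 624 at an unadjusted p under 0.05. The block, slide 1 and slide 2 shifts were 5.25, 5.92 and 4.58 for the first Vitellogenin II probe, 4.02, 4.42 and 3.57 for WDNM1, 2.43, 2.60 and 2.42 for ZP4, and -1.58, -1.39 and -1.81 for dynactin subunit 2. The count fell to 44 without 50 ng/L replicate 2, 41 without 250 ng/L replicate 1, 39 without 250 ng/L replicate 2 and 34 without 50 ng/L replicate 5. With normexp it was 44, and normexp also ended the call of the alpha-mannosidase (adjusted p = 0.142). The Vitellogenin call ended without 250 ng/L replicate 1, 2 or 5 or 50 ng/L replicate 4 or 5 (2.23 to 3.04). Vitellogenin A2 kept its call only without control replicate 1, 2 or 3 or 50 ng/L replicate 1 (2.09 to 2.79 over all 15 arrays left out). A ZP4 probe lost its call without control replicate 1, 2 or 4, 250 ng/L replicate 1, 2, 4 or 5 or 50 ng/L replicate 1, 2 or 5 (1.80 to 2.35). Another did without control replicate 1, 4 or 5, 250 ng/L replicate 1, 2, 4 or 5 or 50 ng/L replicate 1, 2, 4 or 5 (1.58 to 1.90). The ZP3 calls ended without 250 ng/L replicate 1 or 2 or 50 ng/L replicate 5 for the first probe (1.17 to 1.54), and without control replicate 1 or replicate 1, 2, 4 or 5 of either dose for the second (1.06 to 1.36). DAAM1 kept its call only without control replicate 2 or 3 (-0.94 to -0.73). The slide block ended the calls of 1 ZP4 probe (adjusted p = 0.0745) and DAAM1 (adjusted p = 0.0736).

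In the vitellogenin and egg envelope list 4 of 6 genes rose between the doses, and 6 when adjusted over the list alone. The mean shift was 2.32 (camera adjusted p = 2.59e-12; adjusted p = 0.016 with an estimated correlation), 2.38 with slide as a block and 2.68 and 2.06 within slides. All 8 cholesterol synthesis genes were higher, by 0.746 on average (camera adjusted p = 0.000496; adjusted p = 0.428 with an estimated correlation), with 0 past the limma test and 4 when adjusted over the list alone. Their shift was 0.762 with the block and 1.1 and 0.47 within slides, and the call ended within slide 2 (adjusted p = 0.167). In endoplasmic reticulum folding and secretion 26 of 29 genes were higher, by 0.47 on average (camera adjusted p = 1.45e-07; adjusted p = 0.32 with an estimated correlation), with 0 past the limma test and 1 when adjusted over the list alone. The block gave 0.491, and the slides 0.501 and 0.492. Proteasome genes, which encode the protein-degrading complex, had 25 of 32 members higher, by 0.143 on average (0 past the limma test; camera adjusted p = 0.029; adjusted p = 0.972 with an estimated correlation). The block gave 0.149, and the slides 0.105 and 0.214. That call ended without 250 ng/L replicate 1 (0.058) or 4 (0.069) or 50 ng/L replicate 5 (0.127). Oxidative phosphorylation had 68 of 83 genes lower, by a mean of -0.148 (0 past the limma test; camera adjusted p = 0.00398; adjusted p = 0.88 with an estimated correlation). The block gave -0.175, and the slides -0.091 and -0.195. This call ended without 250 ng/L replicate 2 (-0.124), with cyclic loess (adjusted p = 0.114) and with normexp (adjusted p = 0.307). Pancreas markers shifted by 0.091 (camera adjusted p = 0.644).

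The mean of both exposed groups was set against control, with 10 arrays against 5. A probe can pass this contrast through 250 ng/L alone, so passing does not show a change at both doses. Vitellogenin rose by 7.60 ± 0.456 (SE; limma adjusted p = 1.33e-07), Vitellogenin A2 by 7.57, Vitellogenin II by 5.31 and 5.19 on 2 of 3 probes, WAP2 by 4.84, whey acidic protein by 4.31, Serotransferrin I by 4.16 and WAP3 by 4.04. Probes named for gamma-gliadin, App1 and TraD rose by 4.01, 3.98 and 3.96. Beta-galactosidase fell by 2.65 ± 0.44 (adjusted p = 0.00246), and the cytokine A4 homolog by 2.30 ± 0.502 on 1 of 2 probes (adjusted p = 0.0261). Cytoplasmic isocitrate dehydrogenase, an NADPH-producing enzyme, fell by 0.75 ± 0.165 (adjusted p = 0.026), from 2.96 in controls to 2.20 and 2.21 in the exposed groups. Limma called 94 probes, 83 higher and 11 lower, with 562 at an unadjusted p under 0.05. For 80 of the 94, all exposed and control arrays lay beyond the mean of the other side. With slide as a block 89 were called, with 11 within slide 1 and 74 within slide 2. The block, slide 1 and slide 2 shifts were 7.66, 8.44 and 7.09 for Vitellogenin, 4.14, 3.44 and 4.67 for Serotransferrin I, 7.64, 8.49 and 6.96 for Vitellogenin A2, and -0.77, -1.16 and -0.47 for isocitrate dehydrogenase. Mitochondrial ribosomal protein L11 fell by 1.19 (ended with normexp), KIAA0853 by 0.82 on 1 of 2 probes, the cytokine receptor common gamma chain by 0.72 and G patch domain containing 1 by 0.68. KIAA0853 kept its call only without control replicate 2 or 250 ng/L replicate 2 (-0.98 to -0.74), and G patch domain containing 1 only without control replicate 4 or 250 ng/L replicate 4 (-0.77 to -0.58). The cytokine receptor call ended without any 1 of the controls, 250 ng/L replicate 1 or 3 or 50 ng/L replicate 5 (-0.77 to -0.65). That of isocitrate dehydrogenase ended without control replicate 1, 2 or 3 or 50 ng/L replicate 1 or 4 (-0.89 to -0.65), and that of the cytokine A4 homolog without control replicate 3, 4 or 5 or 250 ng/L replicate 4 (-2.49 to -2.02). Cyclic loess also ended the calls of KIAA0853, G patch domain containing 1 and the receptor.

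All 34 probes that rose at 50 ng/L also rose at 250 ng/L, where 126 rose. Independent lists of those sizes would share 0.697. Simulated groups with no effect against the same controls shared 0.01 on average, which had to be small because almost no probe passes there. At an unadjusted limma p under 0.05, 108 probes rose and 57 fell in both comparisons. The simulated groups had 33.6 and 33.4 on average. For all 34 the shift was larger at 250 ng/L, with a median ratio of 1.83 between the log2 shifts for a 5-fold higher concentration. Across the 6145 probes, which are not independent replicates, the shifts at both doses correlated at Pearson r = 0.704 and Spearman rho = 0.556. Over the 5979 probes called at neither dose, Pearson r was 0.574, so called probes raised the value over all probes. Both comparisons use the same 5 controls, and simulation without effect gave a Pearson r of 0.497 and a rho of 0.465 (means of 100 simulations). The covariance was 0.253 against 0.0874 simulated, a difference of 0.165. The simulated probes varied independently of each other. These simulations therefore cannot show how far the correlation, covariance and shared counts vary when probes vary together. Among 100 splits of the real arrays, the real one included, 3 gave a correlation as large as the observed one. With the controls split between the comparisons (20 splits) the mean r was 0.302, from 0.16 to 0.415, and the mean covariance 0.143. Within slide 2 the correlation was 0.523. The same sign was seen for 68.8% of probes, against 66.6% simulated.

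**Figure D3:**
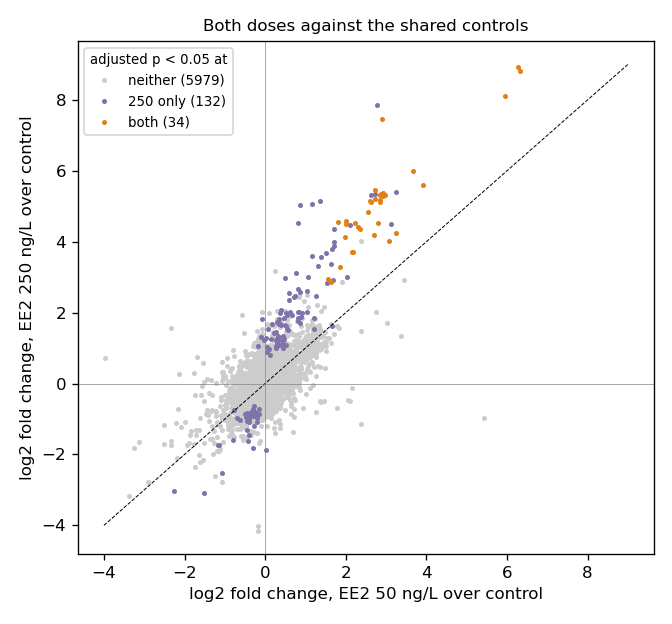
Log2 fold change at 250 ng/L against control (vertical axis) plotted against that at 50 ng/L (horizontal axis), 1 point per probe, with the dashed line marking equal values. The 34 probes called at both doses lie above that line, 132 were called at 250 ng/L alone and 5979 at neither.

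The remaining lists passed no camera test in the comparisons that follow, each p being adjusted over 72 list tests. Estrogen and steroid receptors (4 genes) had adjusted p = 0.644 at 50 ng/L and 0.8 at 250 ng/L. Steroid and bile acid metabolism was at 0.347 at 250 ng/L (adjusted p = 0.47). In it StAR, not well above background on any control array, was at least 2.29-fold higher (fitted shift 2.46 ± 0.329; limma adjusted p = 0.00021). The StAR shift was 2.47 with slide as a block and 1.60 and 3.33 within slides, and its call ended with normexp and within slide 1. Xenobiotic metabolism (45 genes) had a mean shift of -0.147 at 250 ng/L (adjusted p = 0.467). Aryl hydrocarbon receptor 2, a sensor of planar pollutants, was the 1 member that rose, by 1.71 ± 0.363 (limma adjusted p = 0.0157). Its shift was 1.75 with the block and 1.27 and 2.27 within slides, and the call ended with normexp, within either slide and with the pancreas extremes left out. Coagulation and acute phase proteins (33) had adjusted p = 0.0545 at 50 ng/L and 0.629 at 250 ng/L; Serotransferrin I was the 1 member that rose, and 2 did at 250 ng/L when adjusted over the list alone. Lipoproteins (11) had adjusted p = 0.879 and 0.644, complement (20) 0.644 and 0.997, and glycolysis and gluconeogenesis (23) 0.644 and 0.644. The values were 0.832 and 0.813 for fatty acid oxidation (14), 0.99 and 0.99 for the growth and thyroid axis (5), and 0.74 and 0.644 for oxidative and heat stress (31). The 80 ribosomal protein genes shifted by -0.119 at 50 ng/L (adjusted p = 0.281), as -0.946 on slide 1 and 0.433 on slide 2, and by -0.158 at 250 ng/L (adjusted p = 0.173). Quantile normalization gave -0.17 at 50 ng/L (adjusted p = 0.0439). Cell cycle and DNA replication (3 genes) shifted by 1.12 at 250 ng/L (adjusted p = 0.131), with MCM2, a replication helicase subunit, at 2.34 (limma adjusted p = 0.187) and 1 gene past the test when adjusted over the list alone. Without both pancreas extremes it shifted by 1.62 (adjusted p = 0.0253).

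Of the other cell type markers, immune cells (26 genes) had adjusted p = 0.99 at 50 ng/L and 0.644 at 250 ng/L, and ovary and oocyte (5) 0.644 and 0.644. Red blood cell markers (8) had 0.997 and 0.99, with hemoglobin alpha-D the 1 member that fell at 250 ng/L and, when adjusted over the list alone, 1 higher and 1 lower. Intestine markers (3) shifted by -0.799 and -1.19 (adjusted p = 0.156 and 0.196), and intestinal fatty acid-binding protein was at -2.20 (limma adjusted p = 0.191), the 1 lower when adjusted over the list alone. Fatty acid synthesis at 50 ng/L was at 0.417 (adjusted p = 0.131) but passed without control replicate 2 (0.609, adjusted p = 0.0256), as did coagulation and acute phase (0.228, adjusted p = 0.0322). Proteasome genes had adjusted p = 0.99 at 50 ng/L and 0.0974 at 250 ng/L, where they passed without control replicate 2 (0.255, adjusted p = 0.0151). Oxidative phosphorylation at 50 ng/L was at -0.035 (adjusted p = 0.644), as -0.356 and 0.179 within slides. With normexp the median shift of all probes was 0.191 at 50 ng/L, 0.104 at 250 ng/L and -0.141 between the doses, against -0.00614, -0.051 and -0.0465 without it. Under it oxidative phosphorylation, ribosomal proteins and complement were called lower at 50 ng/L than that shifted median (adjusted p = 4.09e-05, 3.6e-07 and 0.00442). Median, mean and test differed in sign for immune, ovary, oxidative stress and proteasome genes at 50 ng/L, for complement, immune and red blood cell genes at 250 ng/L, and for receptor, glycolysis, growth axis, immune and red blood cell genes between the doses. Between the doses, fatty acid synthesis had adjusted p = 0.281, steroid and bile acid metabolism 0.813 and muscle 0.111. The smooth muscle myosin rose by 1.21 (limma adjusted p = 0.0323), a call that ended with slide as a block (adjusted p = 0.0553), without 250 ng/L replicate 2, 3, 4 or 5 and without 50 ng/L replicate 1, 3, 4 or 5 (1.09 to 1.32). It also ended with normexp, quantile normalization, median scaling, cyclic loess and the authors' values.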

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

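The tests of saturated spots, of the slopes of other probes by level, of the correlation between pancreas markers and of their shift between the doses were chosen only after the results were seen. Those of the correlation with ZP4 and of array brightness were set for a pattern already seen in the results. So were those of the slope of the brightest Vitellogenin I probes and of the pancreas marker shift without control replicate 2. An array was singled out where its distance to the nearest other array of its group exceeded Dixon's 95% limit, which chance passes in about 1 of 20 groups: 17 of 216 groups passed it, against 11 expected. Values are the array minus the mean of the other 4 of its group, on the log2 scale. In 50 ng/L replicate 2, App1 protein differed by -1.93, disheveled associated activator of morphogenesis 1 by 0.75, and the list means of endoplasmic reticulum folding and secretion and of fatty acid oxidation by -0.29 and -0.76. In control replicate 2, both probes for WAP four-disulfide core domain protein 3 were higher, by 3.71 and 1.44. In 50 ng/L replicate 5, WDNM1 differed by -2.02 and the second of those probes by -1.78. Estrogen receptor alpha (second probe) differed by -1.51 in 50 ng/L replicate 1, where the percentage of probes well above background was 6.23 points above the mean of the others (87.2% against 81%). Dynactin subunit 2 differed by -0.32 in control replicate 4, KIAA0853 by 0.82 in 250 ng/L replicate 2 and G patch domain containing 1 by 0.56 in 250 ng/L replicate 4. The third Vitellogenin II probe, not called at any dose, differed by -0.43 in 250 ng/L replicate 3. Among list means, immune cell markers differed by -1.49 in control replicate 1, muscle markers by -0.47 in 250 ng/L replicate 1 and ovary and oocyte markers by -0.44 in 50 ng/L replicate 4.

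Probes named for proteins of other organisms rose with the egg envelope probes: 4 for sporozoite surface protein 2 and 1 each for TraD, gamma-gliadin, App1, a DNA translocase and a yeast hypothetical protein were picked after their values were seen, 8 rising by 2.34 to 2.98 at 50 ng/L and 4.37 to 5.32 at 250 ng/L, and 1, not well above background in controls, at least 3.21-fold and 15.8-fold. Over all probes, cyclic loess and quantile normalization moved the median shift at 250 ng/L only from -0.051 to -0.00023 and -0.0867. They are thus a weak test of array brightness, and left 0.995 or more of the median rise of the probes with such names. Within groups their levels correlated with the mean of the ZP4 probes over 15 arrays at a median r of 0.852 (0.438 to 0.919) and rho of 0.782 (permutation p = 5e-05 and 0.00045), 0.716 without the 2 arrays farthest out, and 0.9 and 0.889 within slides, against a median of 0.384 for the other 113 risers. A candidate explanation is that these probes read ZP4 transcripts under names from chance matches. Serotransferrin I (0.874) and 3 Vitellogenin I probes (0.827 to 0.885) correlated with ZP4 as closely, so a shared response to EE2 of separate transcripts stays open; probe sequences were not used here.

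Vitellogenin I probes with the highest signal had the smallest rises: 4.24 and 4.01 at 250 ng/L on the 2 brightest, against 8.11 on the probe with the largest rise. The saturation flag was set on 0 of their spots, and their highest signal was 574113, which argues against saturated spots. Within the exposed groups their level had a median slope of -0.487 on the array's log2 brightness, against -0.145 for 6 other vitellogenin probes. Among probes called at neither dose the median slope was -0.383 for 68 above the same level, where 27.9% lay as low, and 0.00892 for 1256 at levels of 0 to 4, so the slope is shared by bright probes. Control levels were 4.044 and 4.051 on the 2 brightest probes and -1.535 on the probe with the largest rise. At 250 ng/L they were 8.285, 8.061 and 6.575, so these probes differed more in controls. Compression near the top of the signal range is a candidate explanation and would make those rises too small. Different vitellogenin transcripts with different baselines could give such levels too. The levels cannot tell these explanations apart, and different transcripts were not tested and stay open.

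Exocrine pancreas markers were higher in both exposed groups, by 0.989 and 1.08, with 0 genes passing the limma test. Their estimated correlation within groups was 0.755, consistent with pancreatic tissue in different amounts among the livers sampled. Control replicate 2 had the lowest level, -3.38, and without it the shift at 250 ng/L was 0.408, so that 1 array may account for much of the difference. An effect that grows with dose cannot be told apart from no such effect, since the shift between the doses was 0.091 with a standard error of 0.803. Without control replicate 2 and 250 ng/L replicate 3 the shift at 250 ng/L was -0.027, while Vitellogenin and Serotransferrin I still passed the limma test.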

How the results depend on the processing

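Leaving out the 2 pancreas marker extremes, the pancreas marker level as a covariate, and the gene lists as first matched were chosen after the data were seen; the other alternatives were set beforehand. No paired analysis was possible because the labels give no replicate numbers and arrays are numbered within groups only. The count at 50 ng/L was 34, and 3 within slide 1; with 1 array left out it ran from 22 to 36. At 250 ng/L it was 166, and 42 within slide 1, 109 within slide 2, 317 with array weights (197 higher, 120 lower) and 122 to 191 with 1 array left out. Between the doses it was 67, and 44 with normexp, 0 within slide 1, 0 within slide 2 and 34 to 67 with 1 array left out. For the mean of both doses it was 94, and 11 within slide 1, 166 with array weights and 79 to 106 with 1 array left out. Slides 1 and 2 hold 7 and 8 arrays, so the tests within them have fewer arrays; for normexp and array weights the cause was not tested. The weights depend on probe order, and 20 other orders gave 292 to 339 at 250 ng/L and 160 to 169 for the mean. The correlation of the effects at both doses was 0.7036, 0.5235 within slide 2 and 0.6477 to 0.7544 with 1 array left out; the cause was not tested. Camera with an estimated correlation called 1 list at 50 ng/L, 1 at 250 ng/L and 1 between the doses, against 6, 7 and 5 with the preset one; with 1 array left out the numbers were 4 to 7, 5 to 9 and 4 to 6. The estimated correlation widens the variance of lists whose genes vary together (0.755 for pancreas markers). That does not account for every loss. Steroid and bile acid metabolism at 50 ng/L had an estimated correlation of -0.0477 and also lost its call (camera adjusted p = 0.188). The counts of probes, the correlation and the numbers of lists stayed within 1.5 times, or 1 SD, of these values under all other settings run. The shift of hemoglobin alpha-D at 250 ng/L reversed to 0.078 with normexp, and the cause was not tested. Of the named results past the test, 1 of 18 at 50 ng/L, 17 of 40 at 250 ng/L, 0 of 21 between the doses and 3 of 17 for the mean stayed past it in every setting. Across settings, 502 of 539, 1079 of 1194, 483 of 626 and 410 of 491 values kept their direction and side of the threshold, and the rest but hemoglobin kept their direction alone. Signal over background limits the dim probes, with 75.6% to 91.7% of probes well above it on an array. Normexp, which acts most on dim probes, ended the calls of StAR and aryl hydrocarbon receptor 2 at 250 ng/L (shifts of 0.658 and 0.843 in place of 2.46 and 1.71). Its offset of 50 is added to every spot and by itself shrinks the shifts of dim probes. These losses therefore cannot tell whether those shifts are real.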

Other observations

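The genes in this part were chosen after their values were seen, as were the tests of other splits of the arrays. They are single genes, not a tested group, with n = 5 per group. Plasma kallikrein, a serine protease that liver secretes into blood, rose at 250 ng/L by 4.13 ± 0.37 on 1 of 2 probes (SE; limma adjusted p = 3.48e-06; 4.19 with slide as a block, 3.92 and 4.51 within slides). The aspartic proteases cathepsin E and cathepsin D rose by 3.72 and 3.29; their block shifts were 3.79 and 3.31, and within slides they were 4.04 and 3.53, and 3.16 and 3.44. At 50 ng/L, kallikrein, cathepsin E and cathepsin D passed as well (1.98, 2.19 and 1.85; adjusted p = 0.0185, 0.0185 and 0.0495), but none did within either slide, where their shifts were 1.99 and 1.98, 2.25 and 2.14, and 1.71 and 1.95. With slide as a block the shifts were the same, and the cathepsin D call ended (adjusted p = 0.0736). It also ended without any 1 array other than control replicate 1 or 5 (1.61 to 1.96). The kallikrein call ended without control replicate 1 or 3 or 50 ng/L replicate 1, 3 or 5 (1.73 to 1.93). That of cathepsin E ended without control replicate 3 or 4 or 50 ng/L replicate 1 or 3 (1.96 to 2.21). At 250 ng/L aquaporin-12, a water channel, rose by 3.67 (3.59 with the block, 3.02 and 4.24 within slides). Acetyl-coenzyme A synthetase, which makes the acetyl-CoA used in lipid synthesis, rose by 2.60 ± 0.512 on 1 of 2 probes (adjusted p = 0.00856; 2.62 with the block, 2.33 and 2.69 within slides). Within slide 1 the cathepsin D and synthetase calls ended. A cytochrome c oxidase subunit 3 probe rose by 4.47 (4.48 with the block, 4.43 and 4.29 within slides) while the 5 other probes of that name had shifts of -0.39 to 0.23, and it correlated with ZP4 within groups at 0.847.

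Cyclin-dependent kinase inhibitor 1C, which restrains cell division, rose at 250 ng/L by 2.97 ± 0.304 (limma adjusted p = 1.2e-05; 2.99 with slide as a block, 3.10 and 2.79 within slides), against a shift of 0.48 at 50 ng/L. CYR61, a matrix-associated growth regulator, rose on both probes, by 2.43 and 1.83 (2.42 and 1.82 with the block); within slides the shifts were 2.96 and 1.87, and 2.47 and 1.25. The transcription factors early growth response 2b and IRX-5 rose by 1.85 and 2.03 (1.88 and 1.94 with the block, 1.66 and 2.06, and 1.38 and 2.54, within slides). The glycoprotein hormone alpha subunit rose by 1.69 ± 0.294 (adjusted p = 0.00281; 1.64 with the block, 1.63 and 1.55 within slides). With normexp the second CYR61 probe and early growth response 2b no longer passed (adjusted p = 0.117 and 0.316), and within either slide the second CYR61 call ended. Within slide 1 the calls of early growth response 2b, IRX-5 and the hormone subunit ended, the last also within slide 2.

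Other splits of the arrays into groups of the same sizes, 100 for each result with the real one included, were set beside these results. They were drawn without regard to slide, so some may carry differences between the slides. For counts of probes the real split was the 1 as large each time. It gave 34 at 50 ng/L against at most 3 in the others and 166 at 250 ng/L against 30. Between the doses it gave 67 against 4, and for the mean of both doses 94 against 7. A share of 1 in 100 is the smallest these splits can give. Splits that mix the groups also put EE2 effects into the spread, which lowers their counts. Chance is therefore not excluded outright for these counts. The correlation of the effects at both doses, 0.7036, was reached by 3 of 100 splits, 2 of them other than the real one and the highest at 0.7381. That share is under 0.05, but 100 splits give it too roughly to exclude chance for the correlation. For the number of gene lists called chance cannot be excluded either. Of 100 splits, 34 gave as many as the 6 at 50 ng/L (highest other 11) and 19 as many as the 7 at 250 ng/L (highest other 9). Between the doses 43 gave as many as the 5 (highest other 9). For single lists at 250 ng/L, a camera p as small came from 1 split for vitellogenin and egg envelope, 3 for cholesterol synthesis, 6 for endoplasmic reticulum folding and secretion, 13 for muscle, 18 for fatty acid synthesis, 38 for oxidative phosphorylation and 46 for exocrine pancreas. At 50 ng/L it came from 1 for vitellogenin and egg envelope, 1 for steroid and bile acid metabolism, 11 for cholesterol synthesis, 22 for muscle, 35 for exocrine pancreas and 40 for endoplasmic reticulum folding. Between the doses it came from 1 for vitellogenin and egg envelope, 1 for endoplasmic reticulum folding, 4 for cholesterol synthesis, 10 for oxidative phosphorylation and 38 for proteasome genes.

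Lysozyme C, a bacteria-degrading enzyme, had shifts of 3.44 at 50 ng/L and 2.93 at 250 ng/L that did not pass (limma adjusted p = 0.999 and 0.395); they were 8.86 and 7.51 on slide 1 and -0.18 and -0.07 on slide 2. The 5 custom control probes were well above background on 5, 14, 5, 0 and 1 of the 15 arrays. The 1 on 14 arrays had shifts of 0.14 at 50 ng/L and -0.10 at 250 ng/L that did not pass (exact permutation p = 0.698 and 0.794; adjusted p = 0.929 over 10 tests), and the others were too dim to compare.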
